A study of Drosophila melanogaster and Homo sapiens with 8 samples.

How the data were processed

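Sequencing of mRNA was carried out on 8 libraries of 4 groups with 2 libraries each. Whole adult flies (Drosophila melanogaster) carried human alpha-1 antitrypsin (hAAT), a secreted serine protease inhibitor, under a fat body driver, or were controls of a matched genetic background. HCA2 cells, a human fibroblast strain made senescent by X-rays, received either hAAT or phosphate-buffered saline (PBS). Per the labels' protocols, libraries were made with a stranded mRNA kit. Groups were taken from the sample labels.

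The deposited files give 1 count per gene and library, with no normalization, per the values in them. The submitters' processing notes name FastQC, TopHat, Cufflinks and DESeq2 and the genome builds dm6, hg19 and GRCh37, with no versions or roles. The program that made the counts and its strand setting are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping gene on the other strand may not have been told apart. Entries at the end of each file that name no gene stayed out of library sizes and tests. Among uniquely placed reads, the entry for reads outside genes held 1.47% to 1.60% in flies and 11.0% to 11.6% in HCA2 cells. The entry for ambiguous reads held 4.02% to 5.77% and 1.55% to 1.57%. Reads with more than 1 alignment were in an entry of their own, so near-identical genes can be undercounted. A deposited count table of the HCA2 libraries matched the counts of the single files in all cells. The label of PBS replicate 2 numbers it as control 2, and its single file is numbered 3. Its counts equal those of control 2 in the table, and whether a further control library was made is not given in the sources used here. The authors also deposited a DESeq2 comparison of the HCA2 groups, whose columns are log2 fold changes, p-values and a test score, per the file headers. Its direction was checked against the counts.

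Fly gene IDs were placed and named with the Ensembl 115 annotation of BDGP6.54, which has the coordinates of dm6. Of 17559 gene IDs in the files, 17253 had a position and 306 did not. The IDs without a position held 3.58% to 4.98% of the counts and were left out. HCA2 genes were used by the symbols in the files, and no human coordinates are given.

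The counts of 3 fly libraries end at a genome position, in the order 2L, 2R, 3L, 3R, 4 and X. The last counted gene was by (3R, start 9528238) in hAAT replicate 1, Coa8 (X, start 1880282) in hAAT replicate 2 and UQCR-11 (3L, start 25120709) in control replicate 1. Past these positions 0 of 6088, 0 of 2500 and 0 of 6909 annotated genes had a count, while 5288, 2114 and 6017 of the same genes had one in control replicate 2. The zeros there were treated as missing. The fly comparison was therefore limited to the 10306 genes that lie before all 3 positions, on 2L, 2R and most of 3L. This limit was chosen after the data were seen. Library sizes were summed over these genes.

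Each organism was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and groups were compared by the robust quasi-likelihood test, two-sided. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Where no tool is named, a gene that is called or passes, and a count over all genes, refer to edgeR. This left 7432 fly and 14364 human genes. Levels are CPM, the scaled counts of edgeR's cpm function with TMM library sizes, as mean ± SD. The standard error of a log2 fold change is its size divided by the square root of the F statistic. DESeq2 1.42.0 was run on the same genes as an alternative. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of one organism with at least 3 tested members. Camera with an estimated correlation and fry were alternatives. Values of fry are those of its directional test unless its mixed test, which allows changes in both directions, is named.

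The 45 lists, the tests and the rule for named genes were fixed before the data were examined. They hold 22 fly and 23 human lists. The main lists were antimicrobial peptides in flies and cytokines and chemokines of the senescence-associated secretory phenotype (SASP) in HCA2 cells. Named genes are all tested members of the main list, and the 6 of largest fold and 6 of smallest p in each direction among called genes with a mean of at least 1 CPM and no overlap between groups. Up to 4 called members of each other list, or up to 2 uncalled ones as values, were added. Where fewer than 6 genes of a direction were called, the 6 of smallest p were taken as values. The gene w in flies and SERPINA1 in HCA2 cells were added as label checks.

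The alternatives were DESeq2 size factors, library totals, no filter, a mean count of at least 50, non-robust moderation, an adjusted p under 0.1, each library left out in turn and, for HCA2 cells, a replicate block and the series count table. A fit of all fly gene IDs, a fit that added the IDs without a position and a fly fit with the order of the samples as a block were chosen after the data were seen. Leaving out a library left 1 against 2, and the lone library was assumed to vary like the others.

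The steps were tested on simulated counts with known folds. With the 7432 fly genes, edgeR recovered 2, 21, 45 and 49 of 50 genes changed 1.5-fold, 2-fold, 4-fold and 16-fold. It made 14 false calls among 7232 unchanged genes. With the 14364 human genes it recovered 43, 49, 50 and 50 of 50 at the same folds, with 23 false calls among 14164. In both, false calls were a larger share of all calls than the threshold of 0.05. Camera gave an unadjusted p under 0.05 for 1 of 200 random fly lists and 0 of 200 random human lists. Genes were simulated independently of one another, so this does not test camera on lists whose genes vary together. The changed genes were drawn from those with a mean count of at least 50. Each gene was given its estimated dispersion. In the real fly libraries 111 genes differed at least 4-fold with no overlap between groups, and 0 were called. The recovered numbers thus do not carry over to these flies, and 0 calls there do not show that large changes are absent. The estimated correlation was 0.65 for the fly antimicrobial peptides and 0.81 for the HCA2 immediate early genes.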

Results

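Gene expression was measured by RNA sequencing in whole flies that express hAAT and in senescent human fibroblasts treated with hAAT. The series title names anti-inflammatory effects of the protein, and the comparisons ask which genes, immune and inflammatory genes first, differ when it is present. Flies had been kept for 30 to 35 days. HCA2 cells had received 10 Gy of X-rays at 2.56 Gy per minute, were left for 7 days, and were then treated for 5 days with hAAT at 2 mg/mL or with PBS. Each of the 4 groups had 2 libraries. No label says whether the 2 libraries of a group came from separate cohorts or cultures. P-values of single genes thus measure only the spread between these libraries. Camera at the preset correlation compares genes of a list with other genes as if nearly independent. Its p-values therefore rest largely on the spread between genes. No pair of libraries agreed within sampling noise, the chi-square per degree of freedom being 10.7 or more in all pairs. In HCA2 cells, PBS replicate 2 and hAAT replicate 1 (10.8) were closer than the PBS replicates (12.3). The other HCA2 pairs across groups were at 14.7 or more. In flies both replicate pairs (35.3 and 37.7) were closer than any pair across groups (66.8 or more). By median absolute log2 difference, however, fly hAAT replicate 1 and control replicate 2 (0.194) were closer than either replicate pair (0.201 and 0.215).

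Total gene counts were 10496860 and 15483420 in the hAAT flies and 9795730 and 17778628 in the control flies. In HCA2 cells they were 50120670 and 44592143 with PBS and 42991069 and 41471389 with hAAT. The fly totals differ because 3 of the 4 libraries hold no count past a position in the genome. Over the 10306 genes that all 4 fly libraries reach, the counts were 9271209 and 9806654 with hAAT and 9305380 and 9215773 in controls. The right part of 3L past 25120709, 3R, 4 and X are thus outside the fly comparison.

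**Figure D1:**
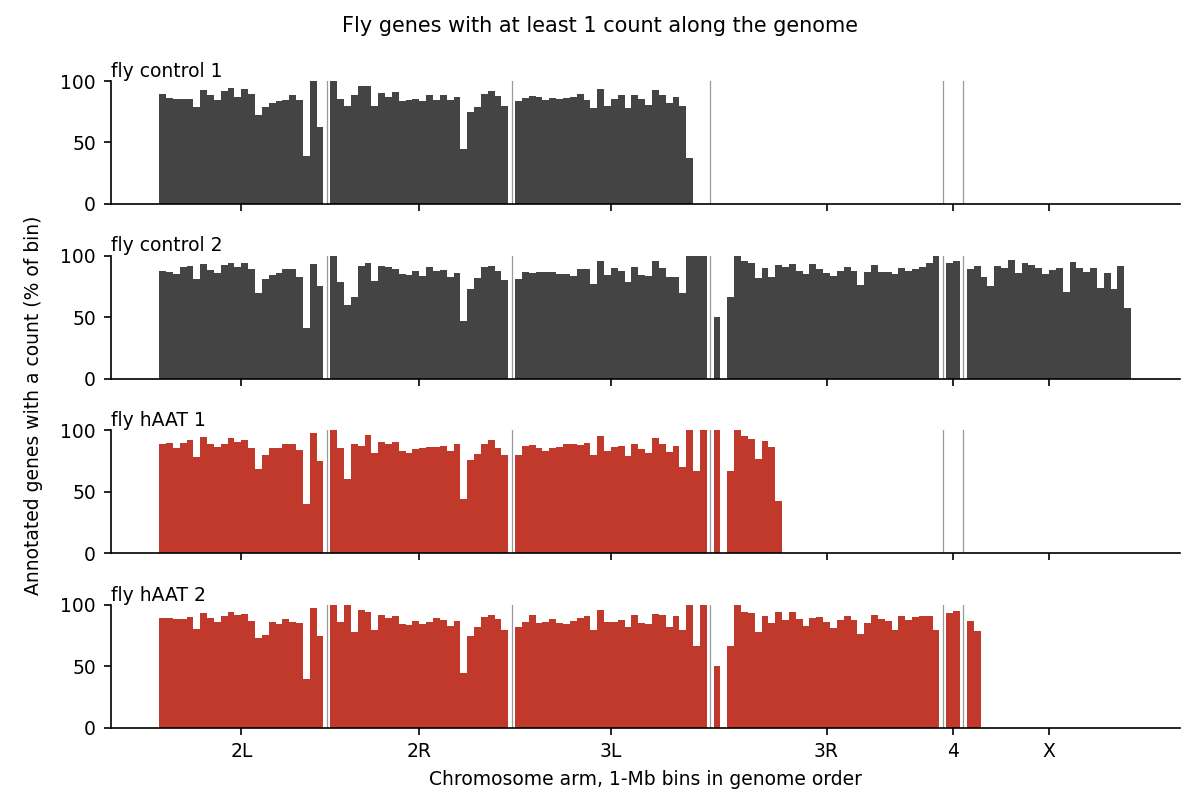
Share of annotated fly genes with at least 1 count (percent, vertical axis) in 1-Mb bins along the chromosome arms (horizontal axis), one panel per library. The bars end on 3L in control replicate 1, on 3R in hAAT replicate 1 and on X in hAAT replicate 2, and go on to the end of X in control replicate 2.

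In hAAT flies, the genes of the antimicrobial peptides, small secreted proteins that kill bacteria and fungi, stood far below their level in control flies. The 8 tested genes had a median log2 fold change of -4.62, and in each of them both hAAT libraries lay below both control libraries. DptA, which encodes a diptericin, was at 5697 ± 738 CPM in controls and 141 ± 146 CPM with hAAT (SD, n = 2 each). Of 17 tested genes of the Toll and Imd pathways, which switch these genes on after infection, 16 had values below 0, with a median of -0.46 (camera adjusted p = 2.54e-10, adjusted p = 0.860 with an estimated correlation). Over all tested genes edgeR called 0 single genes, with 813 at an unadjusted p under 0.05 and 230 called by DESeq2, so these statements rest on gene lists.

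The antimicrobial peptide list fell as a group (camera adjusted p = 3.85e-23, but adjusted p = 0.683 with an estimated correlation and 0.267 with fry). Of its tested members, 8 of 8 were lower adjusted over the list alone. Over all genes tested edgeR called 0 of 8 and DESeq2 8 of 8 (adjusted p from 3.68e-22 for AttC to 0.00437 for AttA). The list names 14 genes: Drs, drosomycin, matched no ID in the files, and the 4 cecropin genes and AttD lie on 3R, outside the part all libraries reach. All 8 tested genes lie on 2R. DptA (FBgn0004240, 18865765 to 18866260) had a log2 fold change of -5.34 (SE 1.01) and its neighbour DptB (FBgn0034407, 18867391 to 18867895) one of -5.02 (SE 0.87). Def, AttC and DptB overlap a gene on the other strand and Mtk overlaps Stacl on its own strand, so part of their counts is uncertain. Dro, drosocin, went from 3257 ± 782 to 107 ± 118 CPM and lies at 14745961 to 14746714. The attacin genes AttA and AttB, which lie next to it and are near-identical so that their reads are uncertain, had log2 fold changes of -1.86 and -3.82. AttC was at 3946 ± 254 CPM in controls and 185 ± 114 CPM with hAAT, or 21.3-fold lower. Mtk, metchnikowin, was 19.6-fold lower and Def, defensin, 28.3-fold lower, from 214 ± 109 to 7.59 ± 4.35 CPM. The hAAT libraries differed from one another: DptA was at 37.96 CPM in replicate 1 and 244 CPM in replicate 2, and the SD of the hAAT group was as large as its mean in DptA, Dro and Mtk.

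In the list of Toll and Imd pathway genes 7 of 17 were lower adjusted over the list alone, and 0 of 17 over all genes tested by edgeR. DESeq2 called PGRP-LC and PGRP-SD of this list over all genes (adjusted p = 8.87e-12 and 1.08e-12). PGRP-SD overlaps 2 other genes, 1 of them on its own strand, so part of its counts is uncertain. PGRP-LC, a receptor for bacterial cell wall fragments, was at 566 ± 63.3 CPM in controls and 185 ± 1.71 CPM with hAAT, and PGRP-SD, a secreted recognition protein, at 185 ± 33.1 and 43.3 ± 5.27 CPM. Short secreted peptides regulated by Toll also fell as a list (13 tested, median -0.68, camera adjusted p = 4.51e-06, adjusted p = 0.683 with an estimated correlation). In this list 7 of 13 were lower adjusted over the list alone, among them BomS5 at 112 ± 8.41 and 62.1 ± 1.49 CPM and Dso1 at 738 ± 108 and 345 ± 36.5 CPM. Serpins, the fly's own serine protease inhibitors, had a median of -0.38 over 24 genes (camera adjusted p = 0.00183, adjusted p = 0.918 with an estimated correlation). Spn27A, which restrains Toll signalling and melanization, was at 258 ± 27.0 CPM in controls and 152 ± 1.41 CPM with hAAT, and Spn42Da at 311 ± 10.5 and 169 ± 0.852 CPM. Only 2 of the 24 serpins were lower adjusted over the list alone, and the list lost its call without control replicate 1 (adjusted p = 0.188).

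Over all 7432 tested fly genes, edgeR called 0 at an adjusted p under 0.05, with 813 at an unadjusted p under 0.05 where chance gives 372. DESeq2 called 230 of the same genes, 70 higher and 160 lower with hAAT. The smallest adjusted p by edgeR was 0.0605, shared by several genes. Among the lower genes of smallest p that did not pass were CG15263 at 204 ± 26.3 and 2.53 ± 1.54 CPM, Mtkl, a metchnikowin-like peptide gene, at 123 ± 3.50 and 8.58 ± 2.94 CPM, and Listericin, an antibacterial protein gene, at 546 ± 98.5 and 86.5 ± 12.8 CPM. CG4269, hzg and GNBP-like3 had log2 fold changes of -2.95, -1.73 and -2.01. Among the higher genes of smallest p, which did not pass either, retinin, an eye-surface protein gene, was at 11.3 ± 1.45 and 67.9 ± 0.136 CPM and Cyp4d8, a cytochrome P450 gene, at 8.89 ± 0.638 and 62.2 ± 8.87 CPM. The others were Sfp24Ba, a seminal fluid protein gene (log2 fold change 2.82), sut4 (1.96), CG13794 (1.86) and ND-B8 (4.52), which overlaps Gs1l on the other strand. No filter gave 22 calls.

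Genes of other tissues were read to describe what the whole-fly RNA held. Testis markers rose as a list (8 tested, median 0.76, camera adjusted p = 0.00662, adjusted p = 0.918 with an estimated correlation). Their summed level was 1220 and 2209 CPM in control replicates 1 and 2 and 1980 and 2575 CPM in the hAAT libraries. The call was lost without control replicate 1 (adjusted p = 0.133) and without hAAT replicate 2 (adjusted p = 0.207). ProtA, a sperm chromatin protein gene, was at 48.5 ± 18.3 and 107 ± 11.8 CPM, and can at 8.80 ± 4.44 and 22.9 ± 1.95 CPM. Male accessory gland genes summed to between 6415 and 14098 CPM and egg shell genes to at most 8.36 CPM in the 4 libraries, and the labels do not give the sex of the flies. The accessory gland list had a median of 0.34 (adjusted p = 0.0855), and passed upward without control replicate 1 (adjusted p = 9.44e-08) or hAAT replicate 2 (adjusted p = 0.0145), with Acp26Ab at 1154 ± 254 and 446 ± 56.6 CPM. Gut markers had a median of 0.21 (adjusted p = 0.586), with LysD and LysP, which overlap other genes, at log2 fold changes of 2.93 and -1.14. Hemocyte markers had a median of -0.28 (adjusted p = 0.586), NimC1 being at 28.1 ± 7.97 and 69.5 ± 1.09 CPM and NimB1 at 28.2 ± 8.34 and 10.5 ± 1.20 CPM. Muscle, neuron and photoreceptor markers had medians of -0.05, 0.07 and 0.02 (adjusted p = 0.602, 0.627 and 0.610). Camera's direction was downward for neuron and photoreceptor markers, whose means were -0.09 and -0.03. Within them Act57B had a log2 fold change of -0.71, ple, the enzyme that starts dopamine synthesis, one of -1.05 and the opsin genes Rh5 and Rh4 of -1.23 and 0.59.

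The remaining fly lists did not pass camera. Fat body secreted and storage genes, from the tissue of the driver, had a median of 0.20 over 9 genes (adjusted p = 0.602, but 1.74e-06 upward without hAAT replicate 2). In it Lsp2, a larval storage protein gene whose promoter drives the transgene, was at 16.01 ± 2.70 CPM in controls and 60.3 ± 64.0 CPM with hAAT, from 106 CPM in replicate 1 and 15.1 CPM in replicate 2. Sugar and lipid digestion had a median of -0.31 (adjusted p = 0.150, but 1.25e-08 without hAAT replicate 1 and 0.0114 without control replicate 2), with Mal-A4 and Mal-A5, both maltases, at -1.07 and -0.78. Cytochrome P450 genes had a median of -0.06 (adjusted p = 0.898), with Cyp4e3 at 1.33 and Cyp28d1 at 1.18. Digestive serine proteases (median 0.04, adjusted p = 0.762, but 0.0351 without hAAT replicate 2), heat shock genes (-0.11, 0.610), endoplasmic reticulum stress genes (-0.07, 0.570), glutathione and antioxidant genes (0.08, 0.602) and insulin and FOXO genes (-0.14, 0.470) were near 0. The 4E-BP gene Thor had a log2 fold change of -0.55 and ImpL2, an insulin antagonist, one of -0.43. Turandot and egg shell lists had 2 tested genes each and the mitochondrial list had 0, so they were not tested as lists. TotM and Socs36E had log2 fold changes of 0.72 and -0.42, and the chorion genes Cp18 and Cp15 of -0.77 and -0.02. The eye colour gene w lies on X (2790599 to 2796466), where only control replicate 2 has counts, so it does not check the labels.

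**Figure D2:**
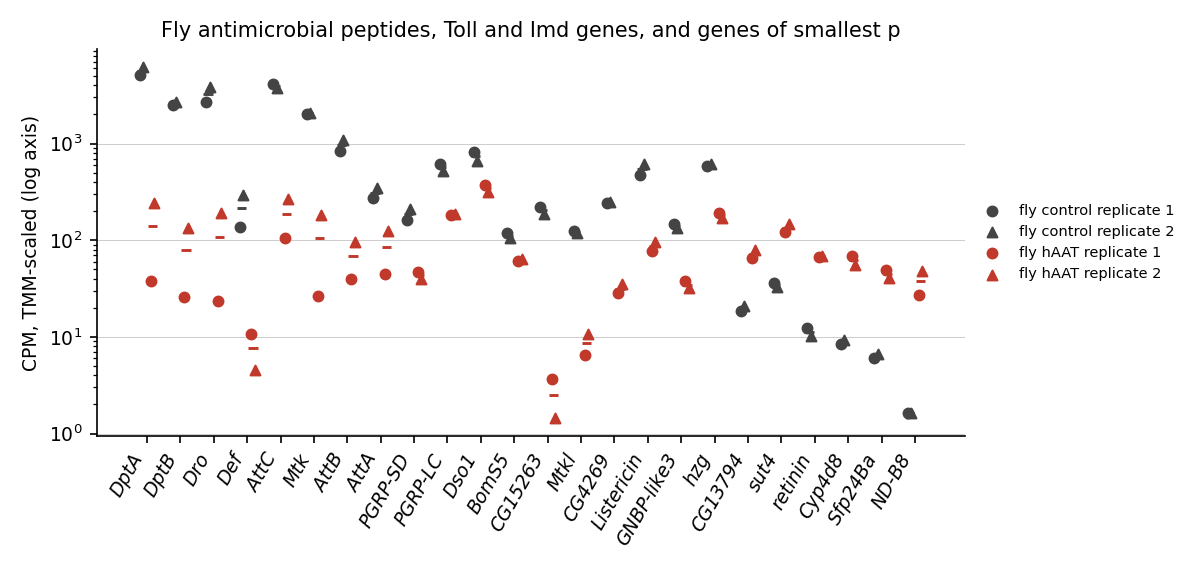
CPM after TMM scaling (log axis) of 24 named fly genes in each library, with control in grey and hAAT in red, circles for replicate 1, triangles for replicate 2 and a line at each group mean. The 8 antimicrobial peptide genes at the left lie lower in both hAAT libraries than in both control libraries, and DptA ranges from 37.96 to 244 CPM with hAAT.

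In senescent HCA2 cells treated with hAAT, 9 of 27 tested SASP cytokine and chemokine genes were called lower by edgeR. This list fell by camera at the preset correlation (adjusted p = 6.34e-59), but not with an estimated correlation (adjusted p = 0.230) or fry (adjusted p = 0.126). Of the 36 genes called by edgeR, 32 were lower and 4 higher, and 9 of the lower ones are SASP cytokines and chemokines. CXCL6, a neutrophil-attracting chemokine, fell from 16.2 ± 2.03 to 5.30 ± 0.987 CPM, or 3.05-fold, and IL6 from 66.6 ± 9.83 to 36.1 ± 4.52 CPM, or 1.85-fold (SD, n = 2 each). SOD2, the mitochondrial superoxide dismutase and a target of NF-kB, fell 1.62-fold and the complement component C3 fell 1.51-fold. The list of p53 targets and senescence regulators had a median of 0.00, and edgeR called none of its 31 genes. It also holds genes that senescent cells lose, such as HMGB1, so its median does not measure the share of senescent cells.

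The SASP cytokine and chemokine list fell (27 tested, median log2 fold change -0.59, camera adjusted p = 6.34e-59, adjusted p = 0.230 with an estimated correlation and 0.126 with fry). In it 9 genes were lower over all genes tested and 15 adjusted over the list alone, and none was higher. In 17 of the 27 both hAAT libraries lay below both PBS libraries, where chance puts 33.3% of genes apart in either direction. CSF3, a granulocyte growth factor, had a log2 fold change of -2.13 (SE 0.24, adjusted p = 3.80e-04), CXCL1 of -1.51 (SE 0.14, adjusted p = 0.00197) and CCL7 of -1.27 (SE 0.12, adjusted p = 5.71e-05). CCL2, the most abundant of them, fell from 682 ± 32.4 to 457 ± 12.6 CPM. IL1B fell from 125 ± 21.8 to 84.1 ± 4.80 CPM, CXCL3 by 1.26 and CXCL5 by 1.21 on the log2 scale. Reads of CXCL1, CXCL2 and CXCL3, which are similar in sequence, are uncertain between the 3 genes. Adjusted over the list alone but not over all genes by edgeR, IL8 was lower at 83.4 ± 17.6 and 33.4 ± 7.38 CPM, CXCL2 at 6.24 ± 2.62 and 2.97 ± 0.484 CPM, IL1A at 15.5 ± 1.89 and 10.8 ± 0.182 CPM and CSF1 at 150 ± 7.04 and 125 ± 8.23 CPM. CSF2 and CXCL10 passed likewise, with log2 fold changes of -0.69 and -1.72. In the authors' DESeq2 comparison IL8 and CXCL2 pass over all genes (adjusted p = 0.00622 and 0.0304). IL1A, CSF1 and CSF2 do not (0.0763, 0.254 and 0.9996), and CXCL10 has no adjusted p there. The other 12 did not pass: LIF, IL11, IL7, CXCL12, CCL13, CXCL11, CCL5, CCL20, CCL26 and IL33 had values from -0.91 to 0.00, and IL15 and TSLP were at 0.08 and 0.31.

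**Figure D3:**
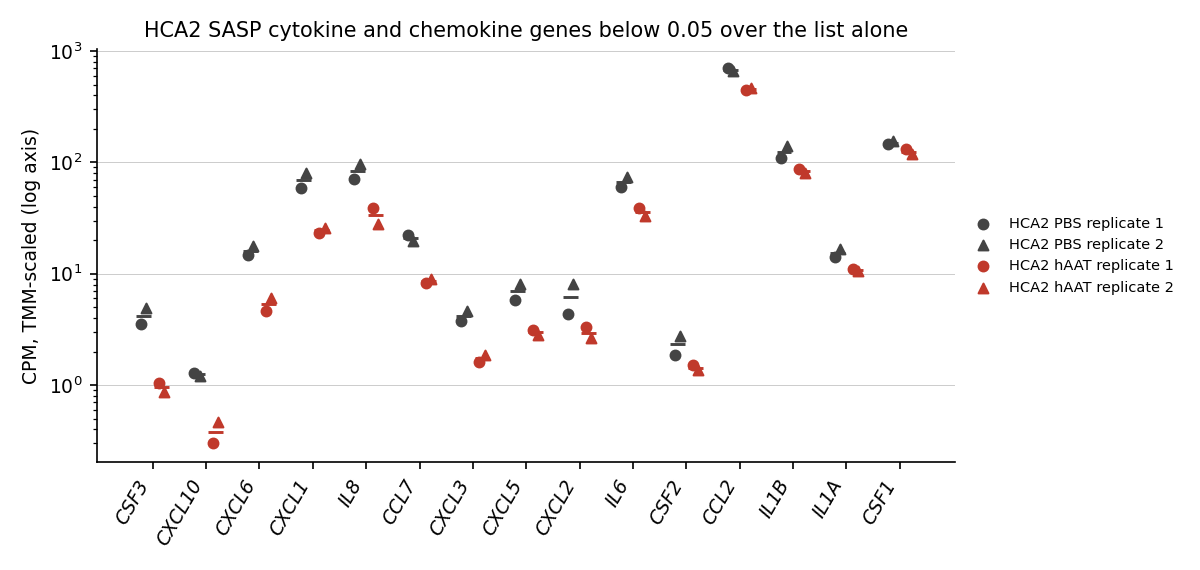
CPM after TMM scaling (log axis) in each HCA2 library for the 15 SASP cytokine and chemokine genes that pass when adjusted over the list alone, with PBS in grey, hAAT in red and a line at each group mean. In all 15, both hAAT libraries lie below both PBS libraries.

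NF-kB targets fell as a list (24 tested, median -0.18, camera adjusted p = 1.71e-18, adjusted p = 0.336 with an estimated correlation), with 3 lower over all genes and 8 adjusted over the list alone. PTX3, a soluble pattern recognition protein, fell from 395 ± 3.41 to 281 ± 9.99 CPM, and ICAM1, a leukocyte adhesion molecule, from 137 ± 3.96 to 105 ± 3.58 CPM. Complement genes fell as a list (14 tested, median -0.10, adjusted p = 2.13e-04, adjusted p = 0.364 with an estimated correlation), C3 alone being called, from 687 ± 32.8 to 456 ± 13.5 CPM. The interferon-stimulated list did not pass (40 tested, adjusted p = 0.257). Its median was 0.06 and its mean -0.05, with camera's direction downward. OASL fell 3.64-fold and IFIT2 1.56-fold in it, and 4 genes were lower adjusted over the list alone. Without PBS replicate 1 that list passed downward (adjusted p = 2.48e-13), and without PBS replicate 2 it passed upward (adjusted p = 5.00e-15). Immediate early genes fell (26 tested, median -0.16, adjusted p = 5.71e-04, adjusted p = 0.646 with an estimated correlation), but not without hAAT replicate 2 (adjusted p = 0.423) or PBS replicate 2, where the direction turned (adjusted p = 0.797). IER3 and ATF3 in it had log2 fold changes of -0.40 and -0.49 and were not called by edgeR. The authors' DESeq2 comparison gives them adjusted p of 0.00495 and 0.525.

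Sterol synthesis genes fell together: 28 of 28 tested genes had values below 0, with a median of -0.22 (camera adjusted p = 9.27e-22, adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone 16 were lower, and over all genes tested 1, FADS1, a fatty acid desaturase, which fell from 218 ± 5.75 to 168 ± 4.13 CPM. No sterol synthesis enzyme of the list was thus called over all genes by edgeR. Glycolysis and hypoxia genes rose (23 tested, median 0.17, adjusted p = 2.94e-10, adjusted p = 0.364 with an estimated correlation), 9 of them adjusted over the list alone and 0 over all genes by edgeR. GAPDH was at 3088 ± 94.9 and 3735 ± 70.0 CPM and PGK1 at 637 ± 49.6 and 794 ± 3.11 CPM. Both pass in the authors' DESeq2 comparison (adjusted p = 0.0316 and 0.0198). Proliferation genes rose by a median of 0.12 (32 tested, adjusted p = 8.84e-10, adjusted p = 0.364 with an estimated correlation), 6 of them adjusted over the list alone and 0 over all genes. KIF20A, a mitotic kinesin, was at 12.8 ± 0.465 and 17.4 ± 1.24 CPM, and CDC20, an activator of the anaphase-promoting complex, at 5.59 ± 0.461 and 8.02 ± 0.0582 CPM.

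Several lists passed with small medians. SASP proteases, inhibitors and growth factors had a median of -0.04 (34 tested, adjusted p = 0.0375, adjusted p = 0.536 with an estimated correlation). Its called member TNFRSF11B, a decoy receptor for the bone-resorption signal RANKL, fell from 874 ± 12.4 to 643 ± 31.1 CPM. The list did not pass without PBS replicate 2 (adjusted p = 0.702) or hAAT replicate 2 (adjusted p = 0.102). Endoplasmic reticulum stress genes had a median of -0.05 (adjusted p = 0.00397, adjusted p = 0.364 with an estimated correlation, 0.0505 without PBS replicate 1), with HSPA5 at -0.17. Lysosome genes had a median of -0.01 (adjusted p = 0.0349, adjusted p = 0.364 with an estimated correlation), and the cathepsins CTSS and CTSK fell by 0.75 and 0.44 on the log2 scale. NRF2 genes had a median of -0.02 (adjusted p = 0.0311, adjusted p = 0.536 with an estimated correlation), with FTH1, ferritin heavy chain, at -0.30 and AKR1C1 at -0.43. Neither gene was called by edgeR. In the authors' DESeq2 comparison FTH1 passes and AKR1C1 does not (adjusted p = 0.0156 and 0.790). The lysosome list did not pass without PBS replicate 1 (adjusted p = 0.153), hAAT replicate 1 (0.0727) or hAAT replicate 2 (0.166). Without the same libraries the NRF2 list did not pass either (adjusted p = 0.324, 0.0927 and 0.110), nor did it with a mean count of at least 50 (adjusted p = 0.0586).

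Outside these lists, the called genes of smallest p were SLC39A8, a zinc transporter, which fell from 72.0 ± 3.93 to 40.1 ± 2.39 CPM (adjusted p = 9.40e-05), and AKR1B1, an aldose reductase, from 418 ± 22.7 to 246 ± 18.5 CPM (adjusted p = 9.40e-05). The 4 higher genes were C4orf3 at 51.4 ± 2.74 and 75.8 ± 3.96 CPM, POLR2J4 at 5.43 ± 0.567 and 10.2 ± 0.000896 CPM, the long noncoding RNA MEG3 at 43.2 ± 0.0365 and 66.2 ± 9.30 CPM and SYTL2 at 38.5 ± 0.961 and 52.4 ± 3.96 CPM. POLR2J4 belongs to a family of near-identical copies, and its reads are uncertain. All of these higher genes lost their calls without PBS replicate 1, while their signs held in that fit. ANGPTL4 and GOLGA8A, next in p, did not pass by edgeR (adjusted p = 0.0509 for both). Both pass in the authors' DESeq2 comparison (adjusted p = 0.0113 and 0.0195).

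The other HCA2 lists did not pass. The p53 list had an adjusted p of 0.531, with HMGB1 at 0.36 and FDXR at 0.17 in log2 fold change. Extracellular matrix genes had a median of 0.05 (adjusted p = 0.482), with DCN, decorin, at -0.34 and LOXL2 at 0.25. TGF-beta response genes had a median of 0.02 (adjusted p = 0.320), with TGFBI at 0.30 and TPM2 at 0.15. Human serpins had a median of 0.01 and a mean of -0.05 with a downward direction (adjusted p = 0.482), with SERPINE2 at -0.30 and SERPINB7 at 0.30. DCN, TGFBI and SERPINE2 were not called by edgeR but pass in the authors' DESeq2 comparison (adjusted p = 0.00714, 0.0183 and 0.0106). LOXL2, TPM2 and SERPINB7 pass in neither. Metallothioneins had a median of 0.04 (adjusted p = 0.724), with MT1L at 0.15 and MT1X at 0.29. Of other cell types, epithelial markers had a median of 0.05 (mean -0.02, upward, adjusted p = 0.339), endothelial markers of -0.12 (0.320), leukocyte markers of 0.21 (0.305) and melanocyte markers of 0.13 (mean -0.01, upward, 0.482). KRT19 and KRT15 were at 0.19 and 0.27, FLT1 and VWF at -0.12 and -0.88, CD68 and PTPRC at 0.11 and 0.51, and KIT and MITF at 0.15 and 0.13. Liver secretory and mitochondrial lists had 0 tested genes. SERPINA1, the gene of the protein itself, had 1 and 1 counts in PBS and 6 and 0 counts in hAAT libraries, so it does not check the labels of cells given the purified protein.

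**Figure D4:**
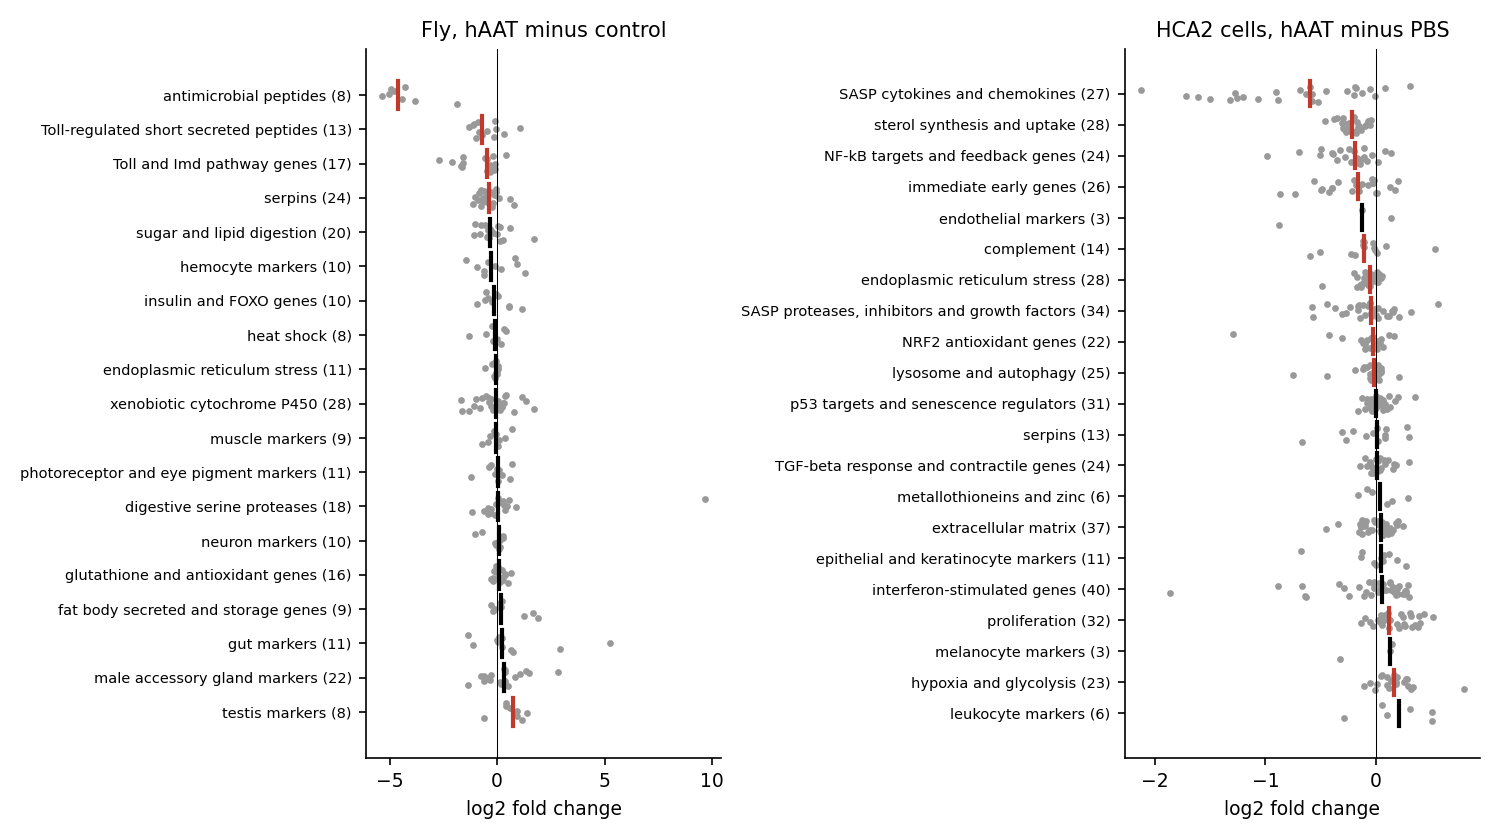
Log2 fold change (horizontal axis) of each tested gene as a grey point, by gene list with the number tested in parentheses, for flies (left) and HCA2 cells (right). Vertical marks are list medians, red where camera's adjusted p at the preset correlation was under 0.05; the antimicrobial peptide median is -4.62 and the SASP cytokine and chemokine median is -0.59.

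The count of called HCA2 genes depended on the libraries and the tool. It was 179 without hAAT replicate 1, 90 of them higher, and 69 without hAAT replicate 2, and DESeq2 called 71, including all 36. In the authors' deposited table of the same comparison, 70 of 15948 genes had an adjusted p under 0.05, 15 higher and 55 lower with hAAT. Of the 15948 genes, 4020 have no adjusted p there and could not pass. Those 70 include all 36 genes called by edgeR. The authors' deposited table gives IL6 a log2 fold change of -0.89 (SE 0.12), CXCL6 one of -1.61 (SE 0.18) and IL8 one of -1.32 (SE 0.31, adjusted p = 0.00622). Their deposited short list holds 45 genes, 6 higher and 39 lower, with adjusted p of at most 0.00885.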

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

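The value reported first here, and the tests of the fly and HCA2 patterns, were chosen after the results were seen, except the test on chromosome neighbours of the antimicrobial peptide genes, which was set before its values were known.

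Outside the part of the genome that every fly library reaches, 4409 genes lie where hAAT replicate 2 and control replicate 2 both have counts. hAAT replicate 1 reaches 821 of these too, which leaves 2 libraries against 1; in an edgeR fit of these 3 libraries, chosen after the data were seen, 0 of the 648 tested were called (41 at an unadjusted p under 0.05), and DESeq2 called 6 higher and 3 lower. The lower ones include Nmdmc and Rel, which lies inside Nmdmc on the same strand, so these are not independent calls. The others stand as 1 library against 1, which leaves no replicate for a test. Among the 2745 of all 4409 at 10 CPM or more in hAAT replicate 2 or control replicate 2, 15 were at least 4-fold higher in hAAT replicate 2 than in the control library and 30 at least 4-fold lower. In the part all libraries reach, the same pair of libraries differed as much in 24 and 42 of 5966 genes, the 2 hAAT libraries in 17 and 22 of 5963, and the 2 control libraries in 1 and 4 of 5902. The lower genes include the cecropins of 3R. CecA1 (30210874) was at 636 CPM in control replicate 2 and 95.6 CPM in hAAT replicate 2, a ratio of 0.150 (95% interval 0.140 to 0.161). CecA2 (30212156), a near-identical copy whose reads are uncertain, had a ratio of 0.00654 (0.00373 to 0.0107), CecC 0.0748 (0.0579 to 0.0952) and AttD 0.0558 (0.0428 to 0.0715). The stress peptide gene TotA had a ratio of 0.477 (0.419 to 0.542) and TotC of 0.141 (0.0935 to 0.207), while TotX of the same family was higher (1.60, 1.09 to 2.39). The Toll-regulated peptide genes BomBc3 and BomT3 were higher too, at ratios of 1.29 (1.14 to 1.45) and 1.26 (1.19 to 1.34). Among the higher genes, CG34138 had counts of 17 and 496 and CG6295 of 522 and 3194. Intervals are exact and cover counting error only.

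The first pattern is the absence of counts past a genome position in 3 fly libraries. Lower depth is argued against, since the smallest ratio of such a library's counts to those of control replicate 2 was 1.01 in the part all libraries reach. Counting that ended at one position is consistent with the data. On the chromosomes after the one where each library ends, 0 genes had a count in it, while 2406 (hAAT replicate 1), 47 (hAAT replicate 2) and 5999 (control replicate 1) of them had one in control replicate 2, and of the last 100 genes before each position that control replicate 2 counts, at least 97 had a count. No biological explanation was tested.

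The second pattern is the low antimicrobial peptide level in hAAT flies. Scaling, which moves all genes of a library alike, is argued against as its cause: the list median was -4.62 and that of all tested fly genes 0.004. The list median was -4.52 with the weaker of the other scalings, but these moved all genes too little to be a test. With them the median of all fly genes was 0.03 and 0.11. Less fat body RNA is argued against too: the lowest of the 9 tested fat body genes was at -0.29. A changed stretch of chromosome around the genes is argued against by 121 tested neighbours within 100 kb, whose median absolute log2 fold change was 0.27 (75th percentile 0.61) against 0.26 over all tested fly genes, and by the 5 separate places where the genes lie. An effect of the transgene, differences of genetic background elsewhere and differences in the microbes the flies met may each remain as open explanations, and none was tested.

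For the third pattern, the lower SASP genes in treated HCA2 cells, scaling, which moves all genes of a library alike, is argued against: the list median lay -0.60 from that of 2497 other genes of the same level (95% interval -1.22 to -0.21). The interval treats the genes of the list as independent and covers the spread among them, not the spread between libraries. Fewer senescent cells cannot be told apart from the treatment, since there are no unirradiated cells to show how far marker genes would move. Of 31 p53 targets and senescence regulators 0 were as low as the list median of -0.59 and the lowest was at -0.16, but proliferation genes rose (median 0.12, adjusted p = 8.84e-10, adjusted p = 0.364 with an estimated correlation), and HMGB1, LMNB1 and HMGB2, which senescent cells lose, were at 0.36, 0.20 and 0.12 without being called. Culture to culture variation of these same genes cannot be told apart from it either: the list's median difference between PBS replicates 2 and 1 was 0.30, and between the hAAT replicates -0.13, with 2 libraries a group. An effect of hAAT, or of anything else in the added preparation, remains open.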

How the results depend on the processing

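The fits of all fly gene IDs, with unplaced IDs added, and with a fly replicate block were chosen after the data were seen; the first 2 gave 0 called fly genes. The 0 fly calls became 22 with no filter, 230 with DESeq2 and 24 at an adjusted p under 0.1, and stayed 0 without each library. The 36 HCA2 calls became 55 with library totals, 151 with no filter, 71 with DESeq2 and 68 at an adjusted p under 0.1, and 26 to 179 without a library. All 36 were called in the first 3 of these, and their signs held in every fit. Without PBS replicate 1, 21 of the 36 were called again, and 25 without PBS replicate 2. ICAM1 and SYTL2 were lost in 3 of the 4 such fits. The labels do not say that equal replicate numbers pair the libraries; with a replicate block, 34 HCA2 genes were called, 31 of them among the 36, and 11 lists, as without it. Across genes, the differences between replicates 1 and 2 had a correlation between the groups of r = -0.02 in HCA2 cells and 0.277 in flies. The fly labels give no replicate numbers, so the order of the samples was taken, and with it as a replicate block 135 fly genes were called (51 higher, 84 lower) against 0 without it, and 7 fly lists against 5. With 2 pairs this does not establish a pairing. Library totals moved the median of all fly genes to 0.11.

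The 5 fly and 11 HCA2 lists called by camera became 0 and 0 with an estimated correlation and 0 and 0 with fry's directional test. By fry's mixed test, which gives no direction, 10 fly and 7 HCA2 lists passed. Among them were lists that camera did not call, such as fly heat shock genes (mixed adjusted p = 0.0110). With an estimated correlation and directional fry, the antimicrobial peptide list had adjusted p of 0.683 and 0.267, and the SASP list 0.230 and 0.126. Their mixed adjusted p were 0.0232 and 0.0398. Without each library they stayed past the threshold, at up to 4.37e-12 and 1.26e-35. Without a library, 4 to 7 fly and 7 to 10 HCA2 lists were called. Adjusted p without a library went from 5.00e-15 to 0.548 for interferon genes and from 1.82e-14 to 0.797 for immediate early genes.

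Uncalled named genes changed sign without a library, over these ranges of log2 fold change: Cp15 -0.50 to 0.68, Socs36E -1.003 to 0.0184, Lsp2 -0.0803 to 2.74, Cp18 -1.31 to 0.12, CCL13 -2.50 to 0.74, MT1L -0.0174 to 0.32, CCL26 -0.99 to 0.35, CXCL11 -0.80 to 1.31, IL7 -0.40 to 0.0780, LIF -0.48 to 0.16, IL15 -0.00330 to 0.15, MT1X -0.0892 to 0.58, IL11 -0.20 to 0.0668 and MITF -0.00979 to 0.25. Cp15 was also at 0.0590 with library totals and 5.60e-04 with DESeq2, and with the replicate block Cp15 was at 0.00948 and CXCL11 at 0.0197. Fits without a library used fewer samples, and fits with no filter tested more genes (9165 fly and 18670 HCA2 genes); the cause of the differences was not tested. Genes under 1 CPM, such as CXCL11, are limited by depth.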

Other observations

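The genes named here were chosen after their values were seen. Besides the genes named by the rule, edin, an infection-induced peptide gene on 3L, was at 64.7 ± 15.5 CPM in control flies and 0.635 ± 0.596 CPM with hAAT, and IBIN, another infection-induced gene on 2R, at a log2 fold change of -6.37. PGRP-SB1, an amidase that cleaves bacterial cell wall, went from 1008 CPM to 153 CPM in mean level. None of the 3 passed over all genes tested by edgeR, with adjusted p of 0.0605, 0.119 and 0.134. Among higher genes, Adh, alcohol dehydrogenase, had a log2 fold change of 2.41 and Ugt49B1, a glycosyltransferase gene, one of 2.20. Neither passed by edgeR, and both did by DESeq2 (adjusted p = 2.13e-06 and 1.82e-15). In all, 111 of 7432 fly genes differed at least 4-fold with no overlap between groups, 61 lower and 50 higher. Of all tested fly genes 49.1% had no overlap, where chance gives 33.3%; in HCA2 cells the share was 33.4%.

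In HCA2 cells further called genes belong to no list fixed beforehand. A second zinc transporter, SLC39A14, fell from 278 ± 18.5 to 213 ± 3.97 CPM. CD36, a fatty acid receptor, FABP3, a fatty acid carrier, and CYP7B1, an oxysterol hydroxylase, fell 1.69-fold, 2.10-fold and 2.13-fold. DPP4, a surface peptidase, fell from 226 ± 5.05 to 148 ± 8.25 CPM, S1PR3, a lipid receptor, from 75.3 ± 6.18 to 49.1 ± 2.06 CPM, and NTN1, a guidance protein gene, from 6.23 ± 0.278 to 3.05 ± 0.423 CPM. CDKN1A, the p21 gene, was at 1610 ± 71.2 and 1574 ± 69.2 CPM, a log2 fold change of -0.03, and was not called.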
